A study of Mus musculus with 12 samples.

How the data were processed

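Motor neurons were identified by cresyl violet and cut by laser from lumbar sections, a pool of cells per mouse, per the labels' protocols. The cDNA was made with SMART-Seq v4, which amplifies full-length transcripts from little RNA, and libraries with Nextera XT, which does not mark strand. Groups and replicate numbers came from the sample titles, 6 KO and 6 WT mice, and each mouse gave 1 library.

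The deposited table gives TPM (transcript abundance normalized for gene length and library total) for 35001 genes in the 12 libraries. Every library sums to nearly the same total, so neither read counts nor depth can be read from it and no counting interval was computed. Per the submitters' processing notes, FastQC, Trimmomatic, DRAGEN and Picard were used with the mm10 build; their roles and versions, the counting step and the annotation are not given in the sources used here. In 12 genes the name held the column separator, and their values were read from the end of the line. No column belonged to another sample, and no 2 libraries were identical.

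From these values, log2(TPM + 1) was computed, with a pseudocount of 1, and 13823 genes with a mean TPM of 1 or more were tested. A fold change is therefore on the log2(TPM + 1) scale, which understates the change of low genes. KO was compared with WT by limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust empirical Bayes and Benjamini-Hochberg adjustment at 0.05, with no block or covariate. Tbk1 and Chat were also tested by an exact two-sided permutation of the difference of mean log2 values over every assignment of the mice to 6 and 6. TPM values share a fixed total, so a change in abundant genes shifts all others slightly; the median log2 fold change of all tested genes was 0.01.

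Of 35 gene lists, 33 had at least 3 tested members and were tested by camera with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Lists, groups, tests and most alternatives were fixed before the data were examined; the exceptions are named where they appear. The naming rule took Tbk1, Chat and Cx3cr1, then the genes past the threshold without predicted-model names, filled to 20 by smallest p, and per described list the members past the threshold, filled to 2 by smallest p. Gene positions came from GENCODE M21 (GRCm38, the assembly of mm10) by symbol for 33760 genes and from a RefSeq table of the same assembly by Entrez ID for 797. Pseudogene transcripts were matched to other transcripts with blastn 2.17.0, at a minimum of 90% identity over 200 bases.

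The procedure was tested on simulated libraries of KO against WT, 6 each and 13823 genes, with 100 genes changed per fold size. Of genes changed 1.5-fold 77% were recovered and of those changed 2-fold 94%, 0% with the wrong sign, and 3.93% of the calls were unchanged genes. The simulated genes varied independently of one another. Alternatives covered the pseudocount, the filter, rescaling, quantile normalization, robust variance, library weights, covariates for Xist and for oligodendrocyte level, a replicate block, a subset of libraries by the number in their description, and each library left out in turn. Xist lay between 0.386 and 0.817 TPM and the Y-linked gene Ddx3y at 0.013 TPM or less in every library. The level of 1 gene is not reported here.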

Results

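RNA was profiled in motor neurons cut by laser from stained sections of the lumbar spinal cord of 20-month-old mice. Each of the 12 libraries came from 1 mouse, 6 labelled Tbk1 knockout (KO) and 6 labelled wild type (WT). Tbk1 encodes TANK-binding kinase 1, a kinase of innate immune signalling and selective autophagy, and its loss-of-function variants are linked to amyotrophic lateral sclerosis (ALS). The labels differ on where the gene was deleted: the design text names motor neurons, its genotype line names a Cre driver of the microglial gene Cx3cr1, the series title speaks of microglia, and all 12 sample descriptions start with ChAT. The libraries held between 13514 and 14241 genes at 1 TPM or more, and mitochondrially encoded transcripts made up 2.6% to 4.35% of TPM. Spearman correlations between libraries, taken across genes, which are not independent replicates, lay between 0.972 and 0.987. Sequencing depth is unknown from these values, because TPM keeps no depth.

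The comparison of KO with WT asked how the RNA of motor neurons differs between aged mice of the 2 genotypes. Tbk1 was almost lost from the KO libraries, at 2.62 ± 0.702 TPM (SD, n = 6) against 38.8 ± 6.52 TPM in WT (SD, n = 6). Chat, which encodes the enzyme that makes acetylcholine, fell from 162.2 ± 10.7 TPM to 86.2 ± 11.6 TPM (SD, n = 6 each). A gene next to Chat, 1700024G13Rik, rose from 0.463 ± 0.223 TPM to 5.39 ± 1.18 TPM, and Ncoa4-ps, a pseudogene of the ferritin receptor gene Ncoa4, rose from 17.1 ± 2.71 TPM to 32.03 ± 1.84 TPM (SD, n = 6 each). These 4 genes, 2 higher and 2 lower, were the ones past the threshold among 13823 tested.

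**Figure D1:**
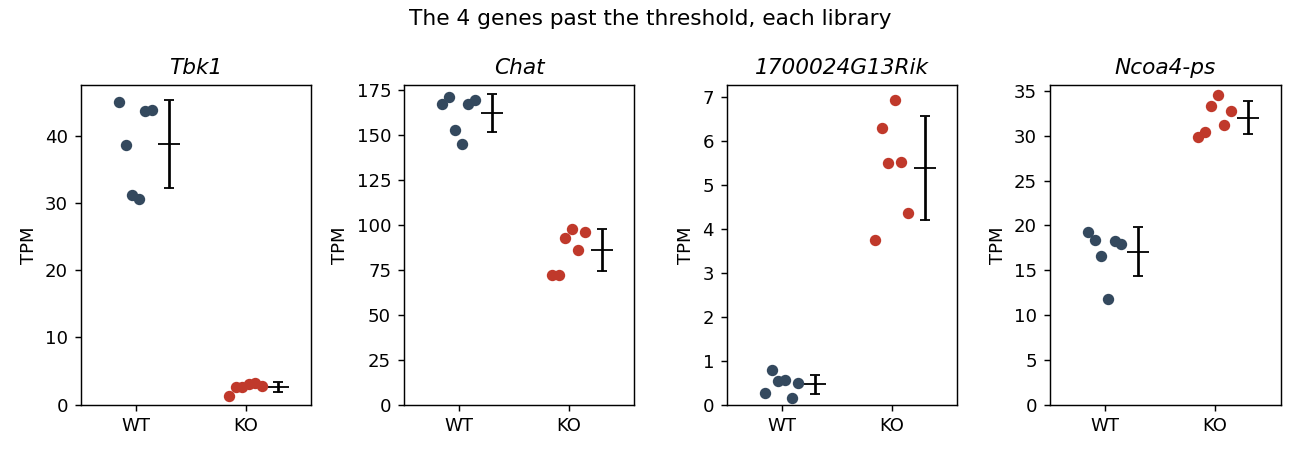
TPM of Tbk1, Chat, 1700024G13Rik and Ncoa4-ps in each WT and KO library (1 point per mouse, 6 per group; the bar beside each group is the mean with 1 SD). KO libraries held 1.30 to 3.29 TPM of Tbk1 and WT libraries 30.5 to 45.0 TPM.

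Tbk1 lies on the minus strand of chromosome 10, from 121546455 to 121586787 (mm10/GRCm38). Its log2 fold change was -3.47 (SE 0.147, limma adjusted p = 1.05e-09). The exact two-sided permutation test gave p = 0.00216, the smallest that 6 mice against 6 allow. KO libraries ranged from 1.30 to 3.29 TPM and WT libraries from 30.5 to 45.0 TPM, so every library matched its label. The values are sums per gene, so the deleted exons were not seen apart from the rest. Cx3cr1, which encodes the fractalkine receptor of microglia (chromosome 9, 119901616 to 120069879), was near the floor in both groups, at 1.36 ± 0.568 TPM in KO and 1.28 ± 0.629 TPM in WT (SD, n = 6 each; log2 fold change 0.05, limma adjusted p = 0.982).

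The other called genes were Chat, 1700024G13Rik and Ncoa4-ps. Chat lies on chromosome 14 from 32408203 to 32465989, on the minus strand, and its log2 fold change was -0.91 (SE 0.0816, limma adjusted p = 2.67e-05). KO libraries kept 53.1% of the WT mean of Chat, and the exact permutation test gave the same smallest p of 0.00216. 1700024G13Rik lies on the same chromosome from 32376068 to 32388391, 19812 bases from Chat, with a log2 fold change of 2.12 (SE 0.142, limma adjusted p = 5.94e-07). It is a predicted-model name, outside the naming rule, and is given because so few genes passed. Ncoa4-ps lies on chromosome 12 from 119260933 to 119264275, with a log2 fold change of 0.88 (SE 0.0996, limma adjusted p = 5.04e-04). Reads of a pseudogene and its parent can be exchanged, so its level is uncertain. Ncoa4 itself, looked up after the values of its pseudogene were seen, stood at 48.2 ± 4.28 TPM in KO and 58.6 ± 4.88 TPM in WT (SD, n = 6 each).

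Genes that missed the threshold fill the rest of the named set. Those with higher values in KO included Ogdhl, a subunit gene of a mitochondrial oxoglutarate dehydrogenase (log2 fold change 0.54, adjusted p = 0.0602), Sgk1, a glucocorticoid-induced kinase (0.63, 0.201), Rpp14 (0.33, 0.215), Haus4 (0.36, 0.284), Thoc7 (0.23, 0.308), Tmem254b (0.38, 0.308) and Ube2e2 (0.26, 0.329), each pair giving the log2 fold change and the limma adjusted p. Those with lower values included Igfbp4, which binds insulin-like growth factors (-0.74, 0.0953), Rprm (-0.44, 0.222), Nkiras1 (-0.24, 0.251), Gadd45b, a stress-induced gene (-0.35, 0.305), and Rgs17 (-0.39, 0.349). The pseudogenes Rtraf-ps (1.48, 0.196), Rpl15-ps6 (4.62, 0.222), Rpl15-ps2 (3.60, 0.222) and Lamtor3-ps (3.57, 0.222) had large differences that missed the threshold, with WT replicate 6 at the KO level. Rpl15-ps6 was 83.4 ± 8.23 TPM in KO (SD, n = 6), 88.3 TPM in WT replicate 6 and 0.432 to 1.17 TPM in the other WT libraries. Of the genes that missed the threshold, Ogdhl, Rpp14, Haus4, Thoc7, Tmem254b, Ube2e2, Nkiras1 and Lamtor3-ps lie on chromosome 14.

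Chromosome 14 held 36 of the 50 genes with the smallest p, 72% against 3.73% of the tested genes, and 34 of them lay between 3 and 33 Mb. Without WT replicate 6 the number of genes past the threshold went from 4 to 43, of which 32 lay on chromosome 14. Lyz2, a lysozyme gene of myeloid cells, Igfbp4, Sgk1 and Dusp1, a phosphatase gene induced early after stimulation, were among the 43, with limma adjusted p of 0.0458, 0.0456, 0.0386 and 0.0265. With all libraries these genes were not called (limma adjusted p of 0.941, 0.0953, 0.201 and 0.570). WT replicate 6 held 8.43 TPM of Lyz2 (KO mean 12.5) and 64.8 TPM of Dusp1 (KO mean 64.5), so leaving it out widened both differences. Lyz2 starts at 117277331 on chromosome 10, which also holds Tbk1 (start 121546455). With the genes of chromosome 14 below 33 Mb left out, an alternative added after the data were seen, 2 genes passed, and 7 passed when WT replicate 6 was left out as well.

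**Figure D2:**
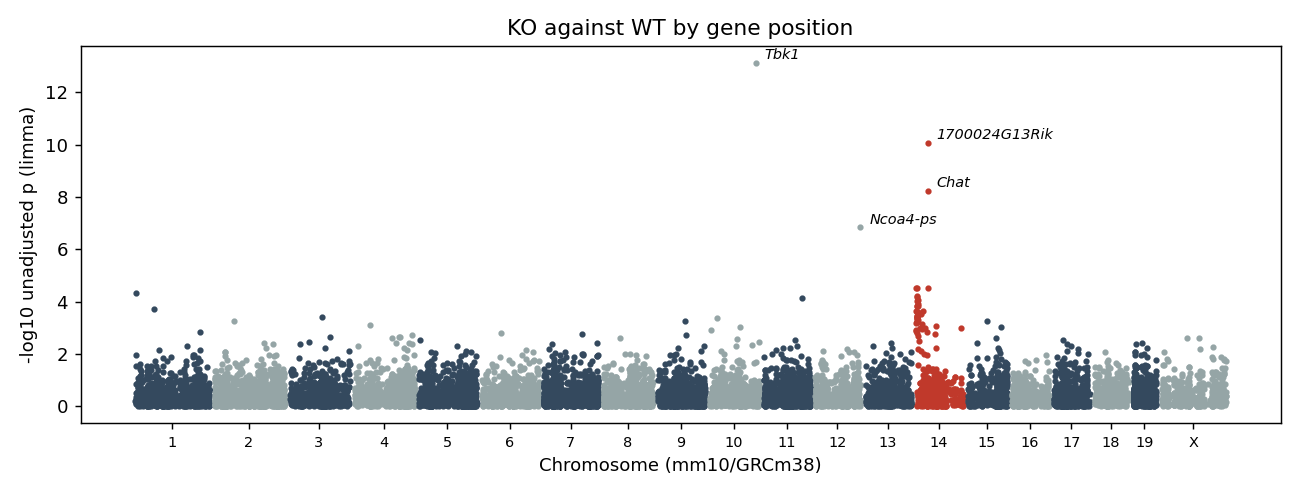
Unadjusted limma p of each tested gene (vertical axis, -log10) by gene start along the chromosomes (horizontal axis, mm10/GRCm38), KO against WT, 6 libraries each, with chromosome 14 in red. Of the 50 genes with the smallest p, 36 lie on chromosome 14.

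**Figure D3:**
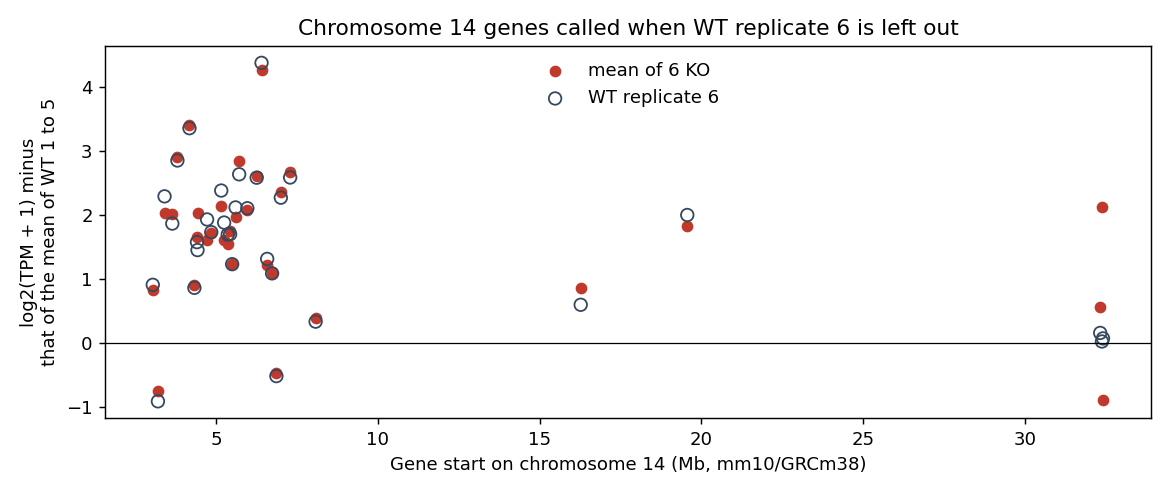
The 32 genes of chromosome 14 past the threshold without WT replicate 6, by gene start (horizontal axis, Mb). The vertical axis is log2(TPM + 1) minus that of the mean of WT replicates 1 to 5, for the mean of the 6 KO libraries (filled) and for WT replicate 6 (open), which lies near KO for the 29 genes between 3 and 20 Mb and near WT for the 3 between 32 and 33 Mb.

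The motor neuron list did not move as a group. Of its 18 tested members, 9 had higher and 9 lower values in KO, with a median log2 fold change of -0.00018 (camera adjusted p = 0.200). Chat was the 1 member called, also when adjusted over the list alone, where 1 gene passed. Lhx4, a homeobox gene of developing motor neurons, had the next smallest p (log2 fold change -0.33, limma adjusted p = 0.907). Other genes of acetylcholine handling, looked up after Chat was seen, did not share its fall: Slc18a3, the vesicular acetylcholine transporter gene nested in Chat, stood at 651.6 ± 83.4 TPM in KO and 620.3 ± 50.7 TPM in WT, and Slc5a7, the choline transporter gene, at 220.3 ± 35.0 and 184.7 ± 21.8 TPM (SD, n = 6 each). Chat and Slc18a3 overlap on the same strand, so reads may have been split between them.

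Markers of microglia, astrocytes and oligodendrocytes had lower values in KO. Of the activated microglia list, 16 of 17 members were lower (median log2 fold change -0.30, camera adjusted p = 4.1e-06), with Lyz2 at -0.85 and Cd52, a leukocyte surface glycoprotein gene, at -0.74. Of the microglia list, 16 of 20 were lower (median -0.18, camera adjusted p = 0.00132), including C1qc (-0.32), a chain of complement C1q, and Tyrobp (-0.38), an adaptor of myeloid receptors. All 14 astrocyte members were lower (median -0.17, camera adjusted p = 0.00129), among them the water channel gene Aqp4 (-0.34) and the filament gene Gfap (-0.48), as were 15 of 17 oligodendrocyte members (median -0.17, camera adjusted p = 0.00355), among them the myelin genes Mobp (-0.26) and Mal (-0.31). The complement list, which shares the C1q genes with microglia, had 5 of 6 lower (median -0.31, camera adjusted p = 0.0115), with Serping1, the C1 inhibitor gene, at -0.33. No member of these 5 lists passed by itself, over all genes or adjusted over the list alone (0 genes). With an estimated correlation none of these 5 lists was called: adjusted p = 0.476 for activated microglia and complement, 0.732 for microglia and astrocytes and 0.788 for oligodendrocytes.

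Markers of other cell types around motor neurons had lower values too, with no call. The mural and fibroblast list had 5 of 5 members lower (median log2 fold change -0.35, camera adjusted p = 0.0563), with the vitronectin gene Vtn at -0.41 and the myosin light chain gene Myl9 at -0.35. The oligodendrocyte precursor list had 5 of 5 lower (median -0.16, camera adjusted p = 0.111), with Tnr, the tenascin R gene, at -0.16 and the transcription factor gene Olig1 at -0.23, and the endothelial list 6 of 8 (median -0.19, camera adjusted p = 0.129), with the tight junction gene Cldn5 at -0.42 and the phospholipid transfer protein gene Pltp at -0.27. No gene of these 3 lists passed over all genes or adjusted over the list alone (0 genes), and WT replicate 3 had the highest level of all 3.

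WT replicate 3 also carried the highest level of each of the 4 glial lists, with 250.2 TPM of Mobp against 123.0 to 144.5 TPM in the other WT libraries. Without it, the microglia (adjusted p = 0.151), astrocyte (0.444), oligodendrocyte (0.737) and complement (0.083) calls ended, and that of the activated microglia list held with the preset correlation (median -0.19, camera adjusted p = 0.000326) but not with an estimated correlation (adjusted p = 0.798). Without WT replicates 3 and 4, left out after the data were seen, the oligodendrocyte list turned higher in KO (median 0.09, camera adjusted p = 0.0351; adjusted p = 0.768 with an estimated correlation) and the astrocyte list lost its direction (median 0.01, adjusted p = 0.832). The number in the sample descriptions, whose meaning the labels do not give, ran from 20 to 43 in KO and from 59 to 70 in 4 of the 6 WT libraries, WT replicates 3 and 6 among them, so it was partly confounded with genotype.

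Blood and early-response genes had higher values in KO. All 6 members of the blood cell list were higher (median log2 fold change 0.61, camera adjusted p = 0.00129), led by the haemoglobin genes Hbb-bt (1.05) and Hbb-bs (1.01; 99.6 ± 39.2 TPM in KO, 48.2 ± 15.1 TPM in WT, SD, n = 6 each). Of the immediate early genes, 7 of 9 were higher (median 0.24, camera adjusted p = 0.00701), led by Dusp1 (0.62) and the transcription factor gene Fos (0.38). No gene of either list passed over all genes, and 2 of each passed adjusted over the list alone: Hbb-bs and Hbb-bt (limma adjusted p = 0.0342), and Dusp1 and Fos (0.0260 and 0.0289). With an estimated correlation both lists had an adjusted p = 0.476. Dusp1 stood at 64.8 TPM in WT replicate 6, close to the KO mean of 64.5 ± 5.09 TPM (SD, n = 6). WT replicate 5, at 58.5 TPM, also lay within the KO range of 56.8 to 72.4 TPM.

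Of the remaining lists, 3 more were called, all lower in KO and by small amounts. The axonal cytoskeleton and transport list had 21 of 26 members lower (median log2 fold change -0.08, camera adjusted p = 0.00132), with the microtubule-associated protein genes Map1b (-0.20) and Map1a (-0.17). The ribosomal protein list had 40 of 46 lower (median -0.05, camera adjusted p = 0.00138), with Rps16 and Rpl14 at -0.15, and lost its call without WT replicate 3 (adjusted p = 0.142). The MHC class I list had 8 of 10 lower (median -0.11, camera adjusted p = 0.0313), with the nonclassical class I genes H2-T22 and H2-T23 at -0.11, and lost its call without WT replicate 6 (adjusted p = 0.0628). With an estimated correlation their adjusted p = 0.732, 0.847 and 0.732, and 0 genes of these lists passed adjusted over the list alone.

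**Figure D4:**
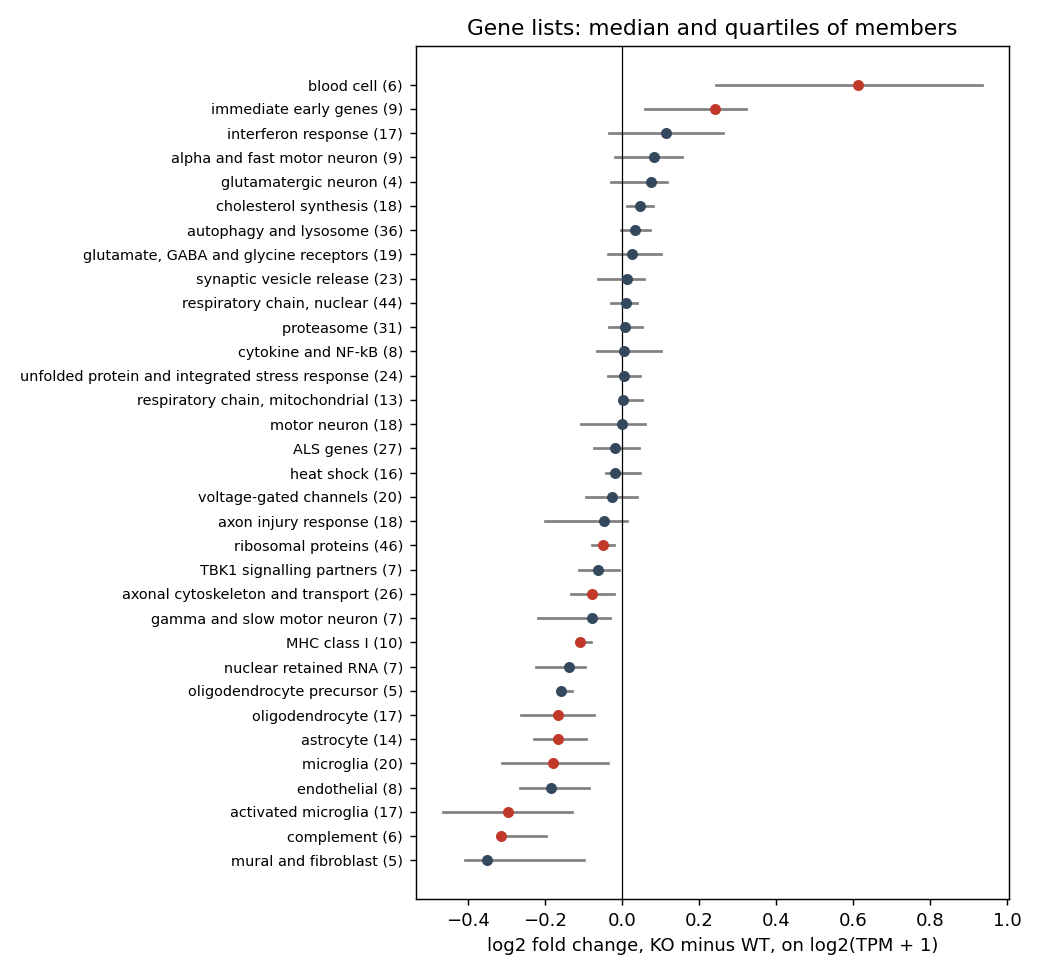
Median log2 fold change of KO minus WT on log2(TPM + 1) (points) and quartiles (lines) of the tested members of each of 33 gene lists, with the number of members in brackets and 6 libraries per group. Red points mark the 10 lists past the threshold by camera with a preset correlation, 8 lower and 2 higher, of which 0 passed with an estimated correlation.

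The lists closest to Tbk1 function were not called. Of the autophagy and lysosome list, 25 of 36 members were higher (median 0.03, camera adjusted p = 0.288), with the autophagy receptor gene Sqstm1 at -0.15 and the autophagy initiation gene Rb1cc1 at 0.20. The TBK1 signalling partners had 6 of 7 lower (median -0.06, adjusted p = 0.294), with Tank at 0.10 and Mavs at -0.17. The interferon response list had 11 of 17 higher (median 0.11, adjusted p = 0.294), with Oasl1 at 0.29 and Rtp4 at 0.26, and the ALS gene list had 18 of 27 lower (median -0.02, adjusted p = 0.294), with the actin-binding gene Pfn1 at -0.15. No gene of these 4 lists passed over all genes or adjusted over the list alone (0 genes).

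Across all genes, 663 had an unadjusted limma p under 0.05, where 691.15 are expected by chance. An exact permutation test per gene called 0 genes (smallest adjusted p = 0.898, 683 at unadjusted p under 0.05). This result carries little information, because the number of assignments bounds each p and Tbk1 was not called either. By limma without robust variance 21 were called. On simulated data of the same size, with 100 genes changed per fold size, 77% of genes changed 1.5-fold and 94% of those changed 2-fold were recovered. Many changed genes ease the adjusted threshold, so these rates do not hold where as few genes pass as here. The median 95% interval of a gene reached 0.23 to each side on the log2 scale. That interval is not adjusted over genes, so a call needed a larger difference in a typical gene. Ogdhl, with a log2 fold change of 0.54, missed the threshold.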

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

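Chosen after the results were seen were the tests of placement on chromosome 14, of WT replicate 6 along it, of a mislabelled library, of Tbk1 and Chat, and the spread of the microglial median; the tests of pseudogene parents, of glial material and of the splits were planned before their results.

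Of 148 groups of 6 libraries, 15 held a library far from the others, where chance gives 7.4; the gap to the nearest library over the range of the group is given for each. The groups are not independent, since lists and their members were both examined and many genes were picked by small p. The excess over 7.4 is therefore not a test. WT replicate 6 was high for Rtraf-ps (0.769), Rpl15-ps6 (0.900), Rpl15-ps2 (0.881), Lamtor3-ps (0.829) and the immediate early gene list (0.646). WT replicate 3 was high for Mobp (0.773), Mavs (0.743), Vtn (0.642) and the astrocyte list (0.642). KO replicate 1 was low for Tbk1 (0.729), Haus4 (0.642) and Snhg11 (0.654). WT replicate 4 was low for Ncoa4-ps (0.687) and high for Cacna1a (0.756), and WT replicate 5 was low for Hbb-bs (0.711).

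Of the 50 genes with the smallest p, 36 lay on chromosome 14 (two-sided Fisher's exact p = 6.7e-41). That test treats genes as independent and so overstates the evidence. Many of the 36 are neighbouring genes with predicted-model names, such as those from Gm10409 (start 3412614) to Gm3739 (start 7293648). These moved together, and the same holds for many of the genes called between 3 and 20 Mb without WT replicate 6. Loss of Tbk1 is argued against for the genes between 3 and 20 Mb, since WT replicate 6, with Tbk1 at 43.75 TPM and so not mislabelled, sat at a median of 1 on a scale from the other WT libraries (0) to KO (1); between 32 and 33 Mb it sat at 0.0212, which does not separate the explanations. Along the 32 genes of chromosome 14 called without WT replicate 6, that library changed level once (1 switch, between 19563800 and 32322019), and a candidate explanation is a stretch of chromosome 14 of another mouse strain, linked to something the KO mice carry on that chromosome (Tbk1 itself lies on chromosome 10) and carried in part by that mouse. The 6 pseudogenes on other chromosomes called without WT replicate 6, of which Ncoa4-ps alone was called with all libraries (the others were Rtraf-ps, Rpl15-ps6, Rpl15-ps2 and, named after their values were seen, Gm6123 and Gm8420), were all closest to coding genes of that stretch (Rpl15, Rtraf, Pdhb and Ncoa4), against 15 of 804 others (two-sided Fisher's exact p = 1.4e-10), so strain differences in reads shared with the parents may account for them. Rpl15-ps6, Rpl15-ps2 and Gm8420 share Rpl15 as their closest gene, so they are not independent in that test. Of the parents, looked up after the values were seen, Ncoa4 was lower in KO (48.2 TPM against 58.6 TPM in WT). Rpl15 (310.3 against 319.6 TPM) and Rtraf (117.8 against 118.1 TPM) hardly differed. Another Rpl15 pseudogene, Rpl15-ps3, also looked up after the values were seen, went the other way without a call. It stood at 93.45 TPM in KO and 164.4 TPM in WT (limma adjusted p = 0.941). No strain is given in the labels used here, and reads would be needed to test for strain differences.

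Tbk1 and Chat fell together, and the labels leave open in which cell Tbk1 was deleted. Fewer motor neurons or a loss of their identity is argued against for Chat, since the other 17 motor neuron genes had a median log2 fold change of 0.00145 (quartiles -0.11 and 0.06). Deletion in microglia alone cannot be told apart by levels, since 9 microglial transcripts had a WT median of 22.6 TPM, 0.625 of the 36.2 TPM of Tbk1 lost, with C1qb at 37.6, Ctss at 32.9, C1qc at 29.96 and C1qa at 22.6 TPM but P2ry12 at 3.04, Tmem119 at 2.55, Csf1r at 2.29 and Cx3cr1 at 1.28 TPM. Over the 6 WT libraries Tbk1 was lower with a higher microglia list level (Pearson r = -0.778, exact permutation p = 0.0264; Spearman rho = -0.886, exact permutation p = 0.0333; r = -0.999 over the 4 libraries left without the 2 farthest), but not beyond chance without WT replicate 3 (r = -0.785, exact permutation p = 0.142), so this does not settle it. An insertion at Chat in the KO mice, such as a Cre driver of motor neurons, stays open as a hypothesis, but sums per gene show no insertion. Of the tested genes within 100 kb of Chat, 1 of 5 passed, and the sample descriptions start with ChAT. The chromosome 14 genes called without WT replicate 6 end at Chat. Haus4, however, also among the 50 genes with the smallest p, starts at 54541785 on that chromosome. Of those 50 genes, 0 lay within 15 Mb of Cx3cr1 on chromosome 9. Few of them lay off chromosome 14 at all, so this result says little.

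Glial lists lay lower in KO. More glial material in WT replicate 3 may account for part of this. Without that library the median of the microglia, astrocyte and oligodendrocyte members went from -0.17 to -0.049. Because WT replicate 3 had the highest level of these lists, leaving it out was bound to shrink the difference. The direction of that shift therefore does not show its cause. Without WT replicates 3 and 4, left out after the data were seen, that median turned to 0.020. The median of the 2 microglial lists stayed lower in KO, at -0.129 without WT replicate 3 and -0.119 without both. Glial material that varies between libraries cannot be told apart from a genotype effect for the 2 microglial lists, whose median went from -0.23 to -0.157 with the oligodendrocyte level as a covariate, within the spread over assignments of the mice (permutation p = 0.238). The number in the sample descriptions, of unknown meaning, is partly confounded with genotype, at 20 to 43 in KO and 59 to 70 in 4 of 6 WT libraries, WT replicate 3 among them; under 50 the median of the microglia, astrocyte and oligodendrocyte members was -0.0506 and that of the 2 microglial lists -0.15. A response of microglia to the genotype stays open and untested.

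The count of genes was seldom reached in other splits of the libraries, and the count of lists often was. The real count of genes includes Tbk1, the gene that defines the groups. The splits therefore do not exclude chance for the other called genes. Of 100 splits of the 12 libraries, 2 called 4 or more genes, the real one included; the other exchanged KO replicate 6 with WT replicate 6 and also called 4 (the highest other), all on chromosome 14 between 3 and 20 Mb. For lists, 37 of 100 splits called as many as the real 10, and the highest other split called 15.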

How the results depend on the processing

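The alternatives that left out genes of chromosome 14, or 2 libraries at once, or joined an estimated correlation to left-out libraries, were chosen after the data were seen. Tbk1 in KO against WT kept its direction and its call in each limma alternative and, as a single gene, by exact permutation with 1 library left out (-2.51 to -3.88; -3.34 to -3.53 with 1 library left out). The 4 called genes stayed called in each limma alternative that tested them. Of the count of genes (4), 21 were called without robust variance, 37 from libraries with a description number under 50 (6 KO, 2 WT, without WT replicates 3 to 6), 2 without the genes of chromosome 14 below 33 Mb, 7 when WT replicate 6 was also left out, and 0 by exact permutation per gene adjusted over all genes, where the number of assignments bounds the p and Tbk1 lost its call too. Leaving out 1 library gave 4 to 43 genes, 43 without WT replicate 6. Of the count of lists (10), 6 were called with a description number under 50, 0 with an estimated correlation (0 also without WT replicate 3 and 0 without WT replicates 3 and 4), 0 by fry in 1 direction and 1 by fry in either, the motor neuron list; leaving out 1 library gave 6 (without WT replicate 3) to 14 (without WT replicate 5).

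Values that turned were not called in these settings, apart from the oligodendrocyte list: Snhg11 0.0564 with Xist as a covariate; Tank -0.0541, Rb1cc1 -0.0675, Pltp 0.0566 and the ribosomal proteins list (test upward, median -0.0143) with a description number under 50; Cx3cr1 -0.0213 without WT replicate 2 and -0.0368 without KO replicate 6, the lowest, against 0.179 without WT replicate 3, the highest; and Olig1 0.0162, Pltp 0.0144, the astrocyte list (0.0121), the oligodendrocyte list (0.0875) and the ribosomal proteins list (test upward, median -0.0111) without WT replicates 3 and 4. The cause was not tested. The replicate numbers did not pair the mice (1 of 6 same-number correlations over 0.1, 1 of 6 KO libraries closest to its own number); with the replicate block 5 genes and 12 lists were called and Tbk1 was -3.47. Depth is unknown, and TPM does not show what it limits.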

Other observations

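The tests named here were planned before the data were examined, and the genes of the first paragraph were chosen after their values were seen.

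Transcripts known from large motor neurons were abundant in both groups, and their means differed by less than the larger SD of the 2 groups. Nefl, the light neurofilament gene, stood at 9432 ± 911 TPM in KO and 9353 ± 662 TPM in WT (SD, n = 6 each), Calca, which encodes the peptide CGRP, at 8350 ± 2258 and 7013 ± 1462 TPM, and Uts2, a urotensin gene, at 4916 ± 969 and 5216 ± 1291 TPM. Spp1, an osteopontin gene used as a marker of alpha motor neurons, stood at 4809 ± 991 TPM in KO and 4823 ± 644 TPM in WT, and Prph, the peripherin gene, at 1486 ± 115 and 1597 ± 63.1 TPM. The alpha and fast motor neuron list had 6 of 9 members higher (median log2 fold change 0.08, camera adjusted p = 0.415) and the gamma and slow list 6 of 7 lower (median -0.08, camera adjusted p = 0.175).

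Receptor and channel genes showed no called change as lists. Of the glutamate, GABA and glycine receptor genes, 11 of 19 were higher (median 0.03, camera adjusted p = 0.741); Grin2b, an NMDA receptor subunit gene, had a log2 fold change of -0.39 and Gabra5, a GABA-A receptor subunit gene, of 0.24 (limma adjusted p = 0.853 for both). Of the voltage-gated channel genes, 12 of 20 were lower (median -0.03, camera adjusted p = 0.175), with Cacna1a at -0.25 and Kcnc1 at -0.20. Of the axon injury genes, 13 of 18 were lower (median -0.05, camera adjusted p = 0.129), with Gadd45a at -0.29 and Stmn4 at -0.23. Of the nuclear retained RNAs, 6 of 7 were lower (median -0.14, camera adjusted p = 0.129), with Malat1 at -0.35. The unfolded protein and integrated stress response genes were 12 higher and 12 lower, with Dnajb9 at 0.11 and Xbp1 at 0.07 (camera adjusted p = 0.939).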
